A study of Mus musculus with 14 samples.

How the data were processed

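RNA abundance was measured by sequencing of total RNA in 14 mouse libraries: fibroblasts from E13.5 embryos (MEF), cells after 7, 18 and 32 days of a chemical protocol (D7, D18 and D32), with 3 libraries each, and primary retinal pigment epithelium (P-RPE) with 2. Per the labels' protocols, RNA was extracted with TRIzol and purified on columns, libraries were made with a NEBNext Ultra RNA kit, and both ends were read for 150 bases on a NovaSeq. Per the labels, the deposited table holds counts, 1 whole number per gene symbol and library, and the values bear this out: they are whole numbers with library totals that differ. The submitters' processing notes name STAR 2.7.11a, featureCounts of the Subread package, edgeR 4.0.16 and limma 3.58.1 and list the builds mm10, GRCm38 and GRCh38, without saying which tool made which value. The strand setting, the treatment of reads with several matches, the annotation release and any merging of gene IDs under 1 symbol are not stated. Near-identical genes and overlapping genes may therefore share reads, and their values are uncertain.

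Groups and replicate numbers were taken from the sample titles. The labels give the MEF libraries the first medium as their treatment, and they give all 14 libraries the same embryonic tissue, P-RPE included; these 2 entries were not used to group samples. A second table, whose 10 columns are human libraries, was not used here. Of 55291 symbols in the mouse table, 53292 (96.4%) matched GENCODE vM21, which gave the coordinates on GRCm38, and 20418 had 0 counts in all libraries. Genes with enough counts were kept with edgeR's filterByExpr by group, which left 20562. The gene lists, the comparisons and the rule for named genes were fixed before the data were examined, apart from lists and genes said below to be added.

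Counts were modelled with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by the trimmed mean of M values (TMM), and 1 quasi-likelihood model with 5 group means and robust dispersions was fitted to all 14 libraries. Each of the 6 comparisons was a contrast of 2 group means, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold, with the number at 2-fold or more given beside it. The SE of a log2 change is its size over the square root of the F statistic. Levels are CPM on the TMM-scaled library sizes. For a gene with 0 counts over all libraries of a group, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts, the ratio is given with an exact 95% counting interval.

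Named genes are the 5 highest and 5 lowest log2 changes among called genes of each comparison with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, 20 lineage genes, and, for each list described, the 2 called members with the largest change each way and the most abundant member that did not pass. The text names some of these, and lineage genes under 1 CPM in both groups were not tried under other settings. Genes named outside this rule, among them the red cell, class II, rod and Y-linked lists, were chosen after their values were seen. There were 36 lists with 511 distinct genes, written from textbook knowledge, and a gene can be in more than 1. They were tested with camera of limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over the 36 lists of a comparison, and again with an estimated correlation and with fry. The count "adjusted over the list alone" applies the Benjamini-Hochberg adjustment to the edgeR p values of the list's own members.

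The position of a library is the median, over genes changed at least 4-fold between P-RPE and MEF, of its log2 CPM (prior count of 2) between the MEF mean at 0% and the P-RPE mean at 100%. D32 and D18 positions were compared by a two-sided exact permutation test. The overlap of the D32 and P-RPE changes from MEF was set beside 20 simulations in which neither group differs from the shared MEF libraries. Parts of the pipeline were tested on simulated data, the positions not among them. With 100 genes changed 2-fold and 100 changed 4-fold, 78% and 98% were recovered for D7 vs MEF with 10 false calls among 19854 genes, and 59% and 89% for D32 vs P-RPE with 13 false calls among 19942. The changed genes were drawn from those above a minimum level in the second group of the comparison. These rates therefore do not cover genes at or near the floor there. A P-RPE share of 15% mixed into simulated D32 libraries was read as 15.7% over 119 genes.

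Alternatives were RLE size factors, library totals alone, no filter on low counts, a mean of at least 5 CPM, the replicate number as a block, DESeq2 1.42.0, limma-voom, a model of the 2 groups alone, and leaving out each library in turn. For positions, the signature threshold and the prior count were also changed. Fits without the D32 or the P-RPE libraries, counts without genes that a P-RPE share could supply, and positions after subtraction of such a share were added after the data were seen.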

Results

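Total RNA was sequenced from 14 mouse libraries in 5 groups. Mouse embryonic fibroblasts (MEF, n = 3) were the starting cells. Treated cells were collected on day 7 (D7, n = 3) and day 18 (D18, n = 3) in a first medium, and on day 32 (D32, n = 3) after a change to a second medium. Primary retinal pigment epithelium (P-RPE, n = 2), the pigmented cell layer that serves the photoreceptors of the retina, was the reference tissue. Per the labels, the first medium held basic FGF, the GSK3 inhibitor CHIR-99021, the BMP receptor inhibitor LDN193189, an inhibitor of TGF-beta receptors, an agonist of the Hedgehog pathway, the DNA methyltransferase inhibitor RG108, the IKK inhibitor BMS-345541 and the casein kinase inhibitor CKI-7. The second medium held Y27632, nicotinamide, retinoic acid and activin A. The labels also say that cells whose induction looked successful were picked for RNA, so the treated groups describe selected cells. They do not say whether the replicates of a group came from separate cultures or animals, so each p measures the spread between samples. That spread was pooled over the 5 groups, which varied unequally. Their common biological coefficient of variation, a measure of relative spread, ran from 0.0426 in MEF to 0.250 at D18. A pooled spread can be too small for the more variable groups.

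Total counts per library ranged from 32352405 to 41390196. The groups spanned 35507532 to 40156109 in MEF, 32352405 to 38425811 at D7, 34560073 to 38085076 at D18, 35263042 to 38151106 at D32 and 40226426 to 41390196 in P-RPE. One count equalled between 0.0227 and 0.0305 CPM after scaling, and the intervals and floors given with folds cover counting error only. Levels are scaled CPM as mean ± SD over the libraries of a group (n = 3, or n = 2 for P-RPE), and changes are on the log2 scale with their SE. The mitochondrially encoded genes took 1.33% ± 0.0569 of the counts in MEF (n = 3), 3.46% ± 0.190 at D7, 1.91% ± 0.317 at D18, 2.64% ± 1.04 at D32 and 2.37% ± 0.651 in P-RPE (n = 2). The most abundant gene was Fn1, which encodes the matrix protein fibronectin, in each MEF library and Gfap, an intermediate filament of astrocytes, in each D18 library. It was Ptgds, a prostaglandin synthase, in both P-RPE libraries.

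Of 20562 genes tested, between 11080 and 14528 changed in each of the 6 comparisons by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p under 0.05. Lists of genes fixed before the data were examined were tested with camera, a competitive test against all other genes. Camera called 94 lists over the 6 comparisons with its preset correlation between genes, and 0 of these calls held with an estimated correlation, where the lowest adjusted p was 0.0772. Camera's calls therefore rest on the preset value, while fry, which asks whether the genes of a list move one way without comparing them with other genes, kept 93 of the 94.

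**Figure D1:**
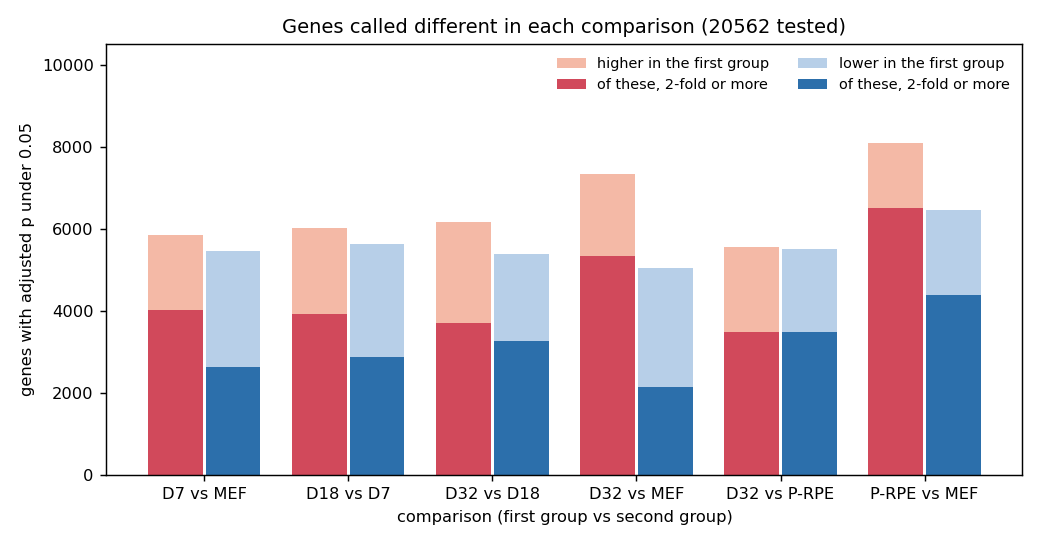
Number of genes (vertical axis) called higher (red) or lower (blue) in the first group of each comparison (horizontal axis), with the darker part of each bar for changes of 2-fold or more. The tallest pair of bars is P-RPE vs MEF, with 8079 genes higher and 6449 lower.

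The first comparison asked what 7 days in the first medium had changed in the fibroblasts. Contractile genes fell, and genes of the Hedgehog pathway and of early neural cells rose. Acta2, the smooth muscle actin of contractile fibroblasts, fell from 4592 ± 128 to 11.5 ± 0.497 CPM, a log2 change of -8.64 (SE 0.25). Gli1, a transcription factor switched on by Hedgehog signalling, rose from 0.373 ± 0.119 to 148 ± 24 CPM, a log2 change of 8.61 (SE 0.55). Sox1, a transcription factor of early neural cells, rose from 0 counts in MEF to 53.3 ± 16.2 CPM, at least 1843-fold. Mki67, a marker of dividing cells, fell from 238 ± 15.7 to 61 ± 17.6 CPM. The adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 3.80e-12 for Acta2, 3.17e-08 for Gli1, 8.88e-09 for Sox1 and 2.49e-06 for Mki67.

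Several lists follow pathways that the first medium acts on. Of the 6 Hedgehog targets, 5 rose, 0 fell and 1 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.00417, adjusted p = 0.334 with an estimated correlation). Of the 16 Wnt targets, 11 rose, 3 fell and 2 did not pass (11 and 3 adjusted over the list alone, camera adjusted p = 4.39e-04, adjusted p = 0.191 with an estimated correlation). Sp5 and Nkd1, which respond to Wnt signalling, rose from 0.0747 ± 0.0647 to 10.6 ± 2.53 CPM and from 4.37 ± 0.329 to 159 ± 18.33 CPM, while Myc fell from 143 ± 5.21 to 59.1 ± 19.3 CPM. Of the 14 TGF-beta and contractile genes, 0 rose, 11 fell and 3 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 6.15e-07, adjusted p = 0.191 with an estimated correlation). Among the 11 BMP targets, 1 rose, 7 fell and 3 did not pass (1 and 7 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.312 with an estimated correlation). Smad6, an inhibitor induced by BMP signalling, fell from 84.6 ± 1.28 to 2.67 ± 0.798 CPM. Of the 18 NF-kappaB and chemokine genes, 14 rose, 1 fell and 3 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 7.96e-04, adjusted p = 0.358 with an estimated correlation). Saa3, an acute-phase gene with 1 count over the MEF libraries, rose to 595 ± 95.1 CPM, a ratio of 61413-fold with a counting interval of 11022 to 2425710.0. Of the 14 immediate early and heat shock genes, which also respond to the handling of cells, 9 rose, 2 fell and 3 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.00764, adjusted p = 0.438 with an estimated correlation). Among the 16 interferon response genes, 15 rose, 0 fell and 1 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 1.62e-07, adjusted p = 0.253 with an estimated correlation). Oasl2, an antiviral gene, rose from 0.587 ± 0.0777 to 62.8 ± 19.2 CPM.

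Markers of neural progenitor and glial cells rose at day 7. The 14 neural retina and neuron markers tested gave no call: 6 rose, 2 fell and 6 did not pass (camera adjusted p = 0.138). Of the 12 neural progenitor genes, 10 rose, 1 fell and 1 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 1.22e-04, adjusted p = 0.191 with an estimated correlation). Each of the 8 glial markers rose: 8 rose, 0 fell and 0 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 2.38e-05, adjusted p = 0.121 with an estimated correlation). Olig2, a transcription factor of oligodendrocyte and motor neuron precursors, rose from 0.0761 ± 0.03 to 138 ± 14.6 CPM. Pax6, a transcription factor of eye and brain, rose from 0.588 ± 0.125 to 15.8 ± 5.3 CPM, and Mitf, the regulator of pigment cells, rose from 3.7 ± 0.0972 to 15.1 ± 0.456 CPM. The retinoid cycle list, which holds the genes with which RPE recycles retinoids, had 7 of 12 members higher at low levels (camera adjusted p = 0.166). Of the 27 cell cycle genes, 0 rose, 27 fell and 0 did not pass (0 and 27 adjusted over the list alone, camera adjusted p = 2.34e-15, adjusted p = 0.121 with an estimated correlation). Among the 35 Hox genes, which mark the position of cells along the trunk, 3 rose, 17 fell and 15 did not pass (4 and 17 adjusted over the list alone, camera adjusted p = 0.00122, adjusted p = 0.422 with an estimated correlation). Of the 11 skeletal muscle markers, 1 rose, 9 fell and 1 did not pass (1 and 9 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.121 with an estimated correlation). Acta1, the actin of skeletal muscle, fell from 122 ± 3.87 to 0.956 ± 0.278 CPM. The fibroblast matrix list was split, with 7 of 19 members higher and 7 lower. Lox, a collagen cross-linking enzyme, fell from 1872 ± 90.3 to 23.9 ± 2.17 CPM, and Dcn, the proteoglycan decorin, rose from 36.7 ± 3.39 to 939 ± 43.5 CPM. Of the 13 mitochondrially encoded genes, some of which have nuclear copies that could share reads, 9 rose, 0 fell and 4 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 0.00834, adjusted p = 0.503 with an estimated correlation).

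Between MEF and D7, 5852 genes rose and 5450 fell, of which 4012 and 2633 by 2-fold or more. Scaling by library totals alone moved the median gene by 0.32 on the log2 scale and gave 8074 higher and 3512 lower, so the higher share went from 51.8% to 69.7%. The majority turned to lower with RLE size factors (5583 higher, 5758 lower), with DESeq2 (5728 and 5910) and without D7 replicate 2 (5083 and 5175).

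From D7 to D18 the medium stayed the same. Gfap, the astrocyte filament, rose from 331 ± 18.9 to 26579 ± 5715 CPM, a log2 change of 6.33 (SE 0.34), and made up 2.02% to 2.92% of all counts at D18. Foxj1, which drives the formation of motile cilia, rose from 34.5 ± 17.3 to 649.9 ± 109 CPM. Mki67 fell further, from 61 ± 17.6 to 3.2 ± 0.853 CPM, a log2 change of -4.25 (SE 0.25). Hmga2, a chromatin protein of embryonic and dividing cells, fell from 179.8 ± 8.38 to 1.43 ± 0.47 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.92e-09 for Gfap, 7.98e-08 for Foxj1, 5.87e-09 for Mki67 and 4.51e-10 for Hmga2.

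Cell division genes were lower still at day 18, and the Hedgehog and Wnt lists that had risen by day 7 fell. Of the 27 cell cycle genes, 0 rose, 27 fell and 0 did not pass (0 and 27 adjusted over the list alone, camera adjusted p = 2.40e-13, adjusted p = 0.148 with an estimated correlation). Bub1, a checkpoint kinase of mitosis, fell from 6.26 ± 1.8 to 0.327 ± 0.244 CPM. Of the 12 cell cycle inhibitors and p53 targets, 1 rose, 9 fell and 2 did not pass (1 and 9 adjusted over the list alone, camera adjusted p = 0.00192, adjusted p = 0.148 with an estimated correlation). Cdkn1a, which encodes the inhibitor p21, fell from 860.2 ± 6.68 to 200.3 ± 49.3 CPM. Among the 6 Hedgehog targets, 0 rose, 6 fell and 0 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 6.85e-04, adjusted p = 0.301 with an estimated correlation). Among the 16 Wnt targets, 0 rose, 13 fell and 3 did not pass (0 and 13 adjusted over the list alone, camera adjusted p = 3.59e-05, adjusted p = 0.148 with an estimated correlation). Lef1, a Wnt effector, fell from 18.07 ± 1.33 to 0.641 ± 0.268 CPM. Of the 11 BMP targets, most of which had fallen by day 7, 8 rose, 0 fell and 3 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 0.0377, adjusted p = 0.585 with an estimated correlation), a call that ended without D18 replicate 1. Of the 16 interferon response genes, 1 rose, 13 fell and 2 did not pass (1 and 13 adjusted over the list alone, camera adjusted p = 0.00246, adjusted p = 0.585 with an estimated correlation). Among the 14 mesenchymal transcription factors, 2 rose, 11 fell and 1 did not pass (2 and 12 adjusted over the list alone, camera adjusted p = 0.0268, adjusted p = 0.237 with an estimated correlation). Twist1, a regulator of mesenchyme, fell from 86.5 ± 24.8 to 35.1 ± 12.6 CPM. Of the 16 glycolysis genes, 10 rose, 0 fell and 6 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 0.00192, adjusted p = 0.585 with an estimated correlation). Slc2a1, a glucose transporter, rose from 61.7 ± 3.63 to 234 ± 58.9 CPM. Of the 13 mitochondrially encoded genes, 0 rose, 10 fell and 3 did not pass (0 and 10 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.709 with an estimated correlation), a call that ended without D18 replicate 2. Of the 8 DNA methylation enzymes, 0 rose, 6 fell and 2 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 0.00297, adjusted p = 0.148 with an estimated correlation).

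Key genes of the RPE were at or near 0 at day 18. Ttr, which carries retinol and thyroxine, and Tyr, the first enzyme of melanin synthesis, had 0 counts in all 3 D18 libraries, which allows at most 0.0855 CPM in a single library. Rpe65, the isomerase of the visual cycle, stood at 0.0377 ± 0.0327 CPM. Of the 11 eye-field transcription factors tested, 0 rose, 3 fell and 8 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.466). Within that list Rax stood at 0.0748 ± 0.0875 CPM, Six3 at 0.208 ± 0.265 CPM and Six6 at 0.0187 ± 0.0324 CPM. Pax6 was at 41.8 ± 3.28 against 15.8 ± 5.3 CPM at D7 and did not pass (adjusted p = 0.0541 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), though it passed with DESeq2's size factors. Among the 22 genes of RPE transport, phagocytosis and secreted factors, 12 rose, 3 fell and 7 did not pass (13 and 3 adjusted over the list alone, camera adjusted p = 0.0377, adjusted p = 0.661 with an estimated correlation). This call ended without D18 replicate 1 or 2, and its largest rise was in Atp1b1, a sodium pump subunit found in many tissues, from 71.7 ± 10.9 to 401 ± 50.4 CPM.

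From D7 to D18, 6011 genes rose and 5634 fell, of which 3917 and 2861 by 2-fold or more. Scaling by library totals alone moved the median gene by -0.21 on the log2 scale and gave 4850 higher and 7059 lower, so the higher share went from 51.6% to 40.7%.

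The change of medium between D18 and D32 came with RPE genes, dividing-cell genes and genes of other tissues. Ttr rose from 0 counts to 2042 ± 597 CPM, at least 73914-fold. Rpe65 rose from 0.0377 ± 0.0327 to 455 ± 228 CPM, Rgr, an opsin of the RPE, rose from 0.0562 ± 0.0973 to 2141 ± 826 CPM, and Tyr rose from 0 counts to 45.9 ± 16.2 CPM, at least 1666-fold. Gfap fell from 26579 ± 5715 to 1539 ± 149 CPM, and Mki67 rose from 3.2 ± 0.853 to 62.4 ± 11.7 CPM. Genes outside the RPE rose in the same libraries: Hbb-bs, an adult beta globin of red cells, went from 0 counts to 76.6 ± 30.3 CPM, and Tie1, a receptor of blood vessel cells, rose from 0.074 ± 0.0862 to 17.9 ± 2.96 CPM. The adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 8.18e-10 for Ttr, 4.02e-08 for Rpe65, 1.23e-06 for Tyr, 4.45e-08 for Gfap and 5.74e-08 for Tie1. In GRCm38 (GENCODE vM21), Rpe65 lies on chromosome 3, start 159599175, end 159625321, Ttr on chromosome 18, start 20665280, end 20674321, and Tyr on chromosome 7, start 87424771, end 87493512.

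Of the 12 genes of the visual cycle and retinoid handling, 11 rose, 0 fell and 1 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 3.84e-06, adjusted p = 0.309 with an estimated correlation). Of the 16 pigmentation genes, 14 rose, 1 fell and 1 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 4.27e-06, adjusted p = 0.309 with an estimated correlation). Dct, an enzyme of melanin synthesis, rose from 0.0178 ± 0.0308 to 395 ± 124 CPM. Among the 22 genes of RPE transport, phagocytosis and secreted factors, 14 rose, 3 fell and 5 did not pass (14 and 3 adjusted over the list alone, camera adjusted p = 0.00397, adjusted p = 0.369 with an estimated correlation). Kcnj13, a potassium channel of the RPE surface, rose from 0.0178 ± 0.0308 to 20.9 ± 6.43 CPM. Otx2, a transcription factor of the eye and forebrain, rose from 0 counts to 73 ± 26.5 CPM, at least 2649.6-fold, while Pax6 was at 35.6 ± 12.5 against 41.8 ± 3.28 CPM at D18 and did not pass. Of the 11 eye-field transcription factors, 7 rose, 1 fell and 3 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.043, adjusted p = 0.385 with an estimated correlation), a call that ended with scaling by library totals or without D18 replicate 3. In the same libraries each of the 9 endothelial markers rose: 9 rose, 0 fell and 0 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 7.59e-06, adjusted p = 0.211 with an estimated correlation). Of the 13 macrophage markers, 11 rose, 1 fell and 1 did not pass (11 and 1 adjusted over the list alone, camera adjusted p = 2.24e-04, adjusted p = 0.315 with an estimated correlation). Ptprc, the common surface antigen of blood leukocytes, rose from 0.057 ± 0.0987 to 8.15 ± 3.02 CPM. The 5 red cell genes (Hbb-bs, Hbb-bt, Hba-a1, Hba-a2 and Alas2), a list added after the data were seen, summed to 143 ± 53.5 CPM at D32 (n = 3), against at most 0.579 CPM in any MEF, D7 or D18 library. The 2 alpha globin genes are near-identical, as are the 2 beta globin genes, so the split within each pair is uncertain.

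Neural progenitor and glial genes of day 18 fell at day 32, while contractile and dividing-cell genes rose. Of the 8 glial markers, 1 rose, 7 fell and 0 did not pass (1 and 7 adjusted over the list alone, camera adjusted p = 5.32e-05, adjusted p = 0.211 with an estimated correlation). Of the 12 neural progenitor genes, 2 rose, 10 fell and 0 did not pass (2 and 10 adjusted over the list alone, camera adjusted p = 1.75e-04, adjusted p = 0.211 with an estimated correlation). Sox2, a factor of neural stem cells, fell from 245 ± 54.5 to 17.5 ± 1.34 CPM. Of the 35 Hox genes, 1 rose, 28 fell and 6 did not pass (2 and 28 adjusted over the list alone, camera adjusted p = 5.61e-09, adjusted p = 0.211 with an estimated correlation). Hoxa5 fell from 27.4 ± 6.32 to 1.93 ± 0.206 CPM. Of the 14 TGF-beta and contractile genes, 13 rose, 0 fell and 1 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 1.98e-06, adjusted p = 0.211 with an estimated correlation). Actg2, an actin of smooth muscle, rose from 0.334 ± 0.286 to 345 ± 169.7 CPM. Of the 17 epithelial junction and keratin genes, 13 rose, 1 fell and 3 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 1.75e-04, adjusted p = 0.211 with an estimated correlation). Dsp, which anchors desmosomes, rose from 0.236 ± 0.167 to 18.4 ± 6.29 CPM. Of the 27 cell cycle genes, 26 rose, 0 fell and 1 did not pass (26 and 0 adjusted over the list alone, camera adjusted p = 1.28e-11, adjusted p = 0.211 with an estimated correlation). Myh2, a myosin of fast skeletal muscle, rose from 0 counts to 935 ± 401 CPM, at least 33737-fold, though the skeletal muscle list gave no call (5 rose, 1 fell and 5 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.131)).

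From D18 to D32, 6151 genes rose and 5374 fell, of which 3693 and 3265 by 2-fold or more. The majority turned with RLE size factors, at 5645 higher and 5860 lower, with DESeq2, at 5727 and 5959, and in a model of the 2 groups alone, at 4727 and 4738, while library totals gave 6759 and 4785. Without the genes whose rise a share of P-RPE RNA of 14.8% could supply, an alternative added after the data were seen, 5489 of 10863 changed genes rose.

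**Figure D2:**
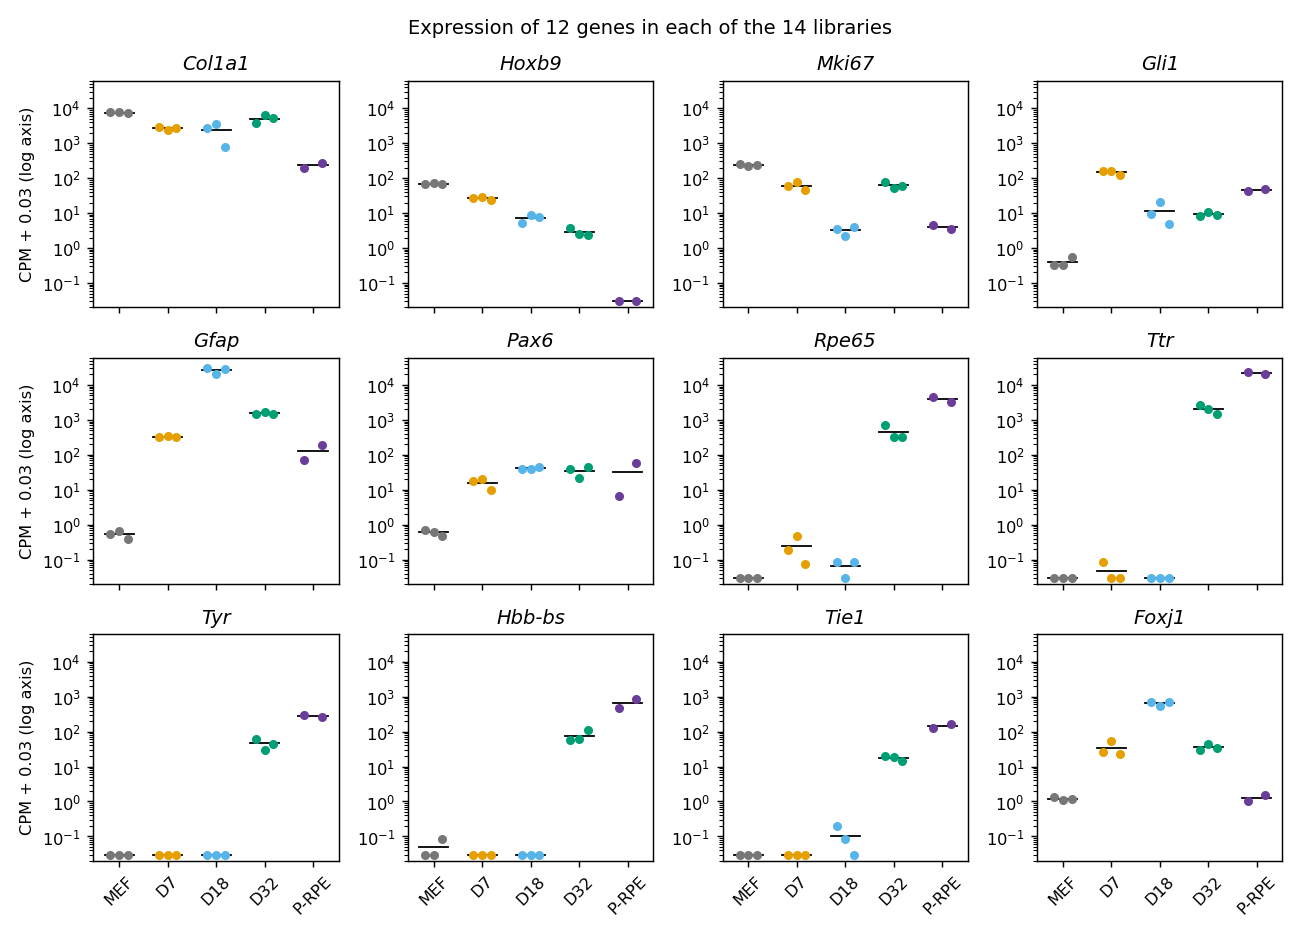
Scaled CPM plus a small constant (vertical log axis) of 12 genes in each library of the 5 groups (horizontal axis), with 1 point per library and a line at the group mean. Rpe65, Ttr, Tyr, Hbb-bs and Tie1 stay at the bottom of their panels in MEF, D7 and D18 and lie higher at D32, where Ttr reaches 2042 ± 597 CPM, and higher again in P-RPE.

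D32 against MEF sets the end of the protocol beside the starting cells. Whether the D32 RNA came from those cells alone stays open, since Y-linked genes set the D32 libraries apart, as given below. Rpe65 rose from 0 counts to 455 ± 228 CPM, at least 15950.2-fold, and Lrat, the enzyme that esterifies retinol in the visual cycle, rose from 0 counts to 278 ± 138 CPM, at least 9741-fold. Mitf rose from 3.7 ± 0.0972 to 21.3 ± 6.45 CPM, a log2 change of 2.52 (SE 0.22), and Pax6 rose from 0.588 ± 0.125 to 35.6 ± 12.5 CPM, a log2 change of 5.92 (SE 0.77). Sim2, a transcription factor, fell from 81.7 ± 3.84 to 0.086 ± 0.0294 CPM, and Prrx1, a factor of limb and trunk mesenchyme, fell from 366 ± 10.9 to 188 ± 47.4 CPM. Col1a1, the main fibrillar collagen chain, was at 5047 ± 1300.1 against 7481 ± 232 CPM in MEF and did not pass. It did pass in a model of these 2 groups alone. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 3.62e-08 for Rpe65, 1.97e-07 for Mitf, 3.28e-05 for Pax6, 1.66e-04 for Prrx1 and 0.219 for Col1a1. Mitf lies on chromosome 6, start 97807052, end 98021349 and Pax6 on chromosome 2, start 105668900, end 105697364 (GRCm38).

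Of the 12 visual cycle genes, 10 rose, 0 fell and 2 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 3.13e-05, adjusted p = 0.281 with an estimated correlation), and of the 16 pigmentation genes, 14 rose, 0 fell and 2 did not pass (14 and 0 adjusted over the list alone, camera adjusted p = 2.08e-05, adjusted p = 0.281 with an estimated correlation). Of the 10 RPE transcription factors, 8 rose, 0 fell and 2 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.281 with an estimated correlation). For RPE transport, phagocytosis and secreted factors, of 22 genes 18 rose, 2 fell and 2 did not pass (18 and 2 adjusted over the list alone, camera adjusted p = 4.78e-04, adjusted p = 0.281 with an estimated correlation). Beside these, of the 9 endothelial markers 8 rose, 1 fell and 0 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.00182, adjusted p = 0.281 with an estimated correlation), and of the 13 macrophage markers 9 rose, 0 fell and 4 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 0.00186, adjusted p = 0.423 with an estimated correlation). Each of the 8 glial markers was higher than in MEF: 8 rose, 0 fell and 0 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 4.38e-04, adjusted p = 0.147 with an estimated correlation). Of the 9 choroid plexus markers, 7 rose, 1 fell and 1 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.00956, adjusted p = 0.11 with an estimated correlation). Clic6 and Enpp2, which are abundant in choroid plexus, rose from 0.195 ± 0.0993 to 159 ± 61.7 CPM and from 3.08 ± 0.83 to 455 ± 155 CPM, and P-RPE held 1434 ± 86.9 CPM and 3859 ± 874 CPM of them. Among the 10 retinoic acid targets, 8 rose, 2 fell and 0 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.0288, adjusted p = 0.281 with an estimated correlation). Cyp26a1, a retinoic acid degrading enzyme, rose from 0.0189 ± 0.0328 to 6.44 ± 1.26 CPM. Of the 14 immediate early and heat shock genes, 9 rose, 1 fell and 4 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.0288, adjusted p = 0.605 with an estimated correlation), a call that ended without D32 replicate 2.

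Groups that mark the starting cell were lower at D32, except the matrix genes. Of the 35 Hox genes, 2 rose, 31 fell and 2 did not pass (2 and 31 adjusted over the list alone, camera adjusted p = 2.33e-14, adjusted p = 0.11 with an estimated correlation). Their summed level went from 505 ± 12.5 CPM in MEF to 51.5 ± 2.21 CPM at D32 (n = 3 each). Of the 14 mesenchymal transcription factors, 1 rose, 11 fell and 2 did not pass (1 and 11 adjusted over the list alone, camera adjusted p = 8.10e-04, adjusted p = 0.096 with an estimated correlation). Of the 27 cell cycle genes, 0 rose, 27 fell and 0 did not pass (0 and 27 adjusted over the list alone, camera adjusted p = 5.82e-17, adjusted p = 0.096 with an estimated correlation). Of the 11 skeletal muscle markers, 1 rose, 10 fell and 0 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 1.42e-04, adjusted p = 0.0772 with an estimated correlation). The fibroblast matrix list gave no call: of 19 genes, 6 rose, 4 fell and 9 did not pass (6 and 4 adjusted over the list alone, camera adjusted p = 0.95). Fn1 was at 7365 ± 1703 against 11073 ± 499 CPM in MEF and did not pass. Thbs1, a matrix protein named after its values were seen, stood at 9407 ± 114 CPM in MEF, 335 ± 91 CPM at D18 and 9353 ± 742 CPM at D32. Y-linked genes also set the D32 libraries apart: the sum of Ddx3y, Eif2s3y, Kdm5d and Uty was 145 CPM in D32 replicate 1, 20.3 CPM in replicate 2 and 152 CPM in replicate 3, against 52.9 ± 1.19 CPM in MEF (n = 3) and 0 in both P-RPE libraries.

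Between MEF and D32, 7325 genes rose and 5051 fell, of which 5346 and 2141 by 2-fold or more. Scaling by library totals alone moved the median gene by 0.20 on the log2 scale and gave 8661 higher and 3869 lower, so the higher share went from 59.2% to 69.1%. Without the genes whose rise a share of P-RPE RNA of 14.8% could supply, 6357 of 11408 changed genes rose.

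P-RPE against MEF defines the distance between target and starting cell. Ttr and Rgr, at 22554 ± 2140.2 CPM and 22241 ± 1562 CPM in P-RPE, had 0 counts in MEF, so that they were at least 782561-fold and at least 771995-fold higher. Hoxb9 and Hoxa5, which had 0 counts in P-RPE, stood at 69 ± 2.26 CPM and 38.17 ± 2.28 CPM in MEF, at least 1681-fold and at least 929-fold lower in P-RPE. Prrx1 was lower, at 10.2 ± 2.09 against 366 ± 10.9 CPM, a log2 difference of -5.17 (SE 0.24). The adjusted p was 7.91e-11 for Ttr, 2.97e-10 for Rgr, 3.32e-11 for Hoxb9 and 9.53e-11 for Prrx1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

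Each of the 12 visual cycle genes was higher in P-RPE: 12 rose, 0 fell and 0 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 1.11e-05, adjusted p = 0.223 with an estimated correlation). Of the 16 pigmentation genes, 15 rose, 0 fell and 1 did not pass (15 and 0 adjusted over the list alone, camera adjusted p = 1.11e-05, adjusted p = 0.223 with an estimated correlation). Each of the 35 Hox genes was lower: 0 rose, 35 fell and 0 did not pass (0 and 35 adjusted over the list alone, camera adjusted p = 6.79e-12, adjusted p = 0.144 with an estimated correlation). Each of the 27 cell cycle genes was lower as well: 0 rose, 27 fell and 0 did not pass (0 and 27 adjusted over the list alone, camera adjusted p = 5.25e-14, adjusted p = 0.138 with an estimated correlation). Of the 19 fibroblast matrix genes, 3 rose, 13 fell and 3 did not pass (3 and 13 adjusted over the list alone, camera adjusted p = 0.00154, adjusted p = 0.564 with an estimated correlation). Of the 14 immediate early and heat shock genes, 11 rose, 2 fell and 1 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.513 with an estimated correlation). Markers of other cells were present in P-RPE beside the RPE genes. Of the 9 endothelial markers, 9 rose, 0 fell and 0 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 5.44e-05, adjusted p = 0.223 with an estimated correlation), and of the 13 macrophage markers, 13 rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone, camera adjusted p = 2.61e-05, adjusted p = 0.223 with an estimated correlation). The 5 red cell genes summed to 1376 ± 569 CPM (n = 2). Sox10, a factor of neural crest, melanocytes and glia, was at 339 ± 7.01 CPM. In this comparison 8079 genes were higher in P-RPE and 6449 lower, of which 6496 and 4386 by 2-fold or more.

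D32 against P-RPE asks what still separated the end product from primary tissue. RPE genes were lower at D32. Ttr stood at 2042 ± 597 against 22554 ± 2140.2 CPM, a log2 difference of -3.46 (SE 0.26), and Rpe65 at 455 ± 228 against 3897 ± 943 CPM, a log2 difference of -3.10 (SE 0.40). Mitf was at 21.3 ± 6.45 against 96.8 ± 8.7 CPM and Otx2 at 73 ± 26.5 against 528 ± 90.2 CPM. Pax6 and Six6 did not pass, with log2 differences of 0.11 (SE 0.62) and -0.63 (SE 0.80). The P-RPE libraries differed for Pax6, at 6.58 and 59.6 CPM, and without replicate 2 its log2 difference was 2.44 and passed. Fibroblast genes were higher, with Col1a1 at 5047 ± 1300.1 against 238 ± 55.1 CPM, a log2 difference of 4.41 (SE 0.53), and Fn1 at 7365 ± 1703 against 82.7 ± 35.5 CPM. The adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.15e-06 for Ttr, 6.11e-05 for Rpe65, 1.16e-06 for Mitf, 1.49e-05 for Otx2 and 1.27e-05 for Col1a1.

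Each of the 12 visual cycle genes was lower at D32: 0 rose, 12 fell and 0 did not pass (0 and 12 adjusted over the list alone, camera adjusted p = 8.30e-09, adjusted p = 0.216 with an estimated correlation). Of the 16 pigmentation genes, here and in the rest of the paragraph counted as higher (rose) or lower (fell) at D32, 0 rose, 13 fell and 3 did not pass (0 and 14 adjusted over the list alone, camera adjusted p = 9.72e-08, adjusted p = 0.216 with an estimated correlation). Of the 11 eye-field transcription factors, 0 rose, 7 fell and 4 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.217 with an estimated correlation). Markers of blood vessels and macrophages were lower along with the RPE genes. Of the 9 endothelial markers, 0 rose, 8 fell and 1 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 4.06e-06, adjusted p = 0.216 with an estimated correlation), and each of the 13 macrophage markers was lower: 0 rose, 13 fell and 0 did not pass (0 and 13 adjusted over the list alone, camera adjusted p = 2.59e-06, adjusted p = 0.217 with an estimated correlation). Of the 19 fibroblast matrix genes, 16 rose, 1 fell and 2 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 4.06e-06, adjusted p = 0.452 with an estimated correlation). Of the 35 Hox genes, 32 rose, 0 fell and 3 did not pass (32 and 0 adjusted over the list alone, camera adjusted p = 4.68e-10, adjusted p = 0.216 with an estimated correlation). Of the 27 cell cycle genes, 26 rose, 0 fell and 1 did not pass (26 and 1 adjusted over the list alone, camera adjusted p = 6.34e-11, adjusted p = 0.216 with an estimated correlation). Of the 14 TGF-beta and contractile genes, 12 rose, 0 fell and 2 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 1.75e-05, adjusted p = 0.217 with an estimated correlation). Of the 14 immediate early and heat shock genes, 1 rose, 9 fell and 4 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 0.0294, adjusted p = 0.605 with an estimated correlation), a call that ended with fry or without P-RPE replicate 2. Of the 22 oxidative phosphorylation genes, 0 rose, 15 fell and 7 did not pass (1 and 16 adjusted over the list alone, camera adjusted p = 8.12e-04, adjusted p = 0.488 with an estimated correlation). Ndufa4, a subunit of the respiratory chain, was at 112 ± 6.97 against 195 ± 19.3 CPM.

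The D32 level of genes restricted to P-RPE was also set against their P-RPE level. For 115 genes chosen on P-RPE, MEF, D7 and D18 alone, with at least 20 CPM in P-RPE and at most 1% of that level in MEF, D7 and D18, the median D32 level was 11.2% of P-RPE, with a 10th to 90th percentile of 4.84% to 17.4% and a range of 1.59% to 104%. The medians per library were 14.8%, 9.92% and 8.77%. The 22 members of the RPE lists among them had a median of 11.8% and a range of 8.62% to 36.6%. The red cell genes lay at 9.83%, the 3 endothelial markers Pecam1, Tie1 and Cldn5 at 13.5%, and 4 class II antigen presentation genes at 17.4%. The other endothelial markers did not meet the rule for restricted genes and lay at 14.7% to 93.0%, the highest being Emcn, at 99.5 ± 14.8 against 107 ± 3.47 CPM. The classes differed in order between the D32 libraries: in replicates 1, 2 and 3 the RPE list genes lay at 16.1%, 10.8% and 8.69%, the red cell genes at 6.83%, 9.37% and 14.04%, and the class II genes at 18.6%, 21.9% and 11.01%. The 10 rod photoreceptor genes lay at 1.99%, with 0.571%, 2.09% and 3.26% in replicates 1, 2 and 3.

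**Figure D3:**
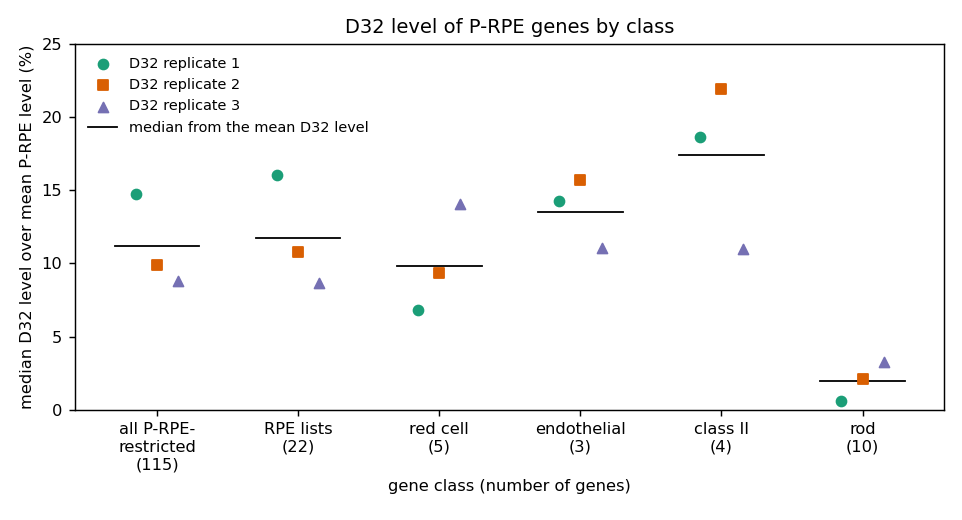
Median D32 level as a percentage of the mean P-RPE level (vertical axis) for 6 classes of gene (horizontal axis), with 1 point per D32 library and a line for the value from the mean of the D32 libraries. RPE list genes (11.8%), red cell genes (9.83%), endothelial markers (13.5%) and class II genes (17.4%) lie above the rod genes (1.99%).

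Between D32 and P-RPE, 5564 genes were higher at D32 and 5516 lower, of which 3491 and 3480 by 2-fold or more. Scaling by library totals alone moved the median gene by 0.23 on the log2 scale and gave 6979 higher and 4260 lower, so the higher share went from 50.2% to 62.1%. More genes were lower than higher with RLE size factors (5080 higher, 5983 lower), with DESeq2 (5255 and 5923), with limma-voom (5452 and 5934) and without P-RPE replicate 1 (4361 and 4543).

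The D32 and P-RPE changes from MEF overlapped: 5679 genes were higher and 4163 lower in both, and 532 went opposite ways. A share of P-RPE RNA of 14.8% at D32 could by itself supply the rise of part of these genes, and without those 4712 were higher in both. Independent lists of these sizes would share 2878 and 1584 genes. Both comparisons use the same 3 MEF libraries, which alone makes their changes covary. Over 20 simulations with unchanged groups against those libraries, the log2 changes correlated by 0.439 and 64.7% of genes had the same sign, against 0.792 and 80.1% in the data. The simulated changes are noise alone, so 0.439 is not the part of 0.792 that the shared libraries supply. The covariance of the log2 changes was 0.0539 in the simulations and 5.45 in the data. In the simulations a mean of 0 genes was called higher in both and 0 lower in both. Of 4569 genes at least 4-fold higher in P-RPE than in MEF, 3692 (80.8%) had risen by D32, of which 2907 (63.6% of the 4569) beyond such a share, 4 had fallen, and 2844 (62.2%) were still below P-RPE. Of 2327 genes at least 4-fold higher in MEF, 1494 (64.2%) had fallen by D32 and 120 had risen, and 1840 (79.1%) were still above P-RPE. Beyond this axis, 1604 genes were higher at D32 than in both MEF and P-RPE, and 771 were lower than in both.

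On the P-RPE-higher genes, with 0% at the MEF mean and 100% at the P-RPE mean, the median position was 28.7% ± 3.54 at D7, 56.6% ± 1.55 at D18 and 59.4% ± 3.04 at D32 (SD, n = 3). An alternative added after the data were seen subtracted a share of P-RPE RNA, set for each D32 library at its median fraction of the P-RPE-restricted genes. D32 then stood at 40.4% ± 1.71, below D18 at 56.6%, so the order of D32 and D18 turned. The library sizes were left unchanged, which lowers this value by an amount that was not measured. On the MEF-higher genes the median position, without subtraction, was 35.7% ± 1.83 at D7, 69.8% ± 3.06 at D18 and 37.3% ± 2.12 at D32 (SD, n = 3). The D32 libraries thus lay nearer to MEF than the D18 libraries did. A two-sided exact permutation test between D32 and D18 gave p = 0.3 for the P-RPE-higher and p = 0.1 for the MEF-higher genes, and 0.1 is the smallest p that 3 against 3 libraries allow. With genes of at least 5 CPM on average, the order on the P-RPE-higher genes turned, with D32 at 62.5% and D18 at 69.8%. It also turned with a signature of 2-fold or more, with 57.7% and 60.4%. With a signature threshold of 4 on the log2 scale the order held and widened, with D32 at 62.2% and D18 at 44.7%.

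**Figure D4:**
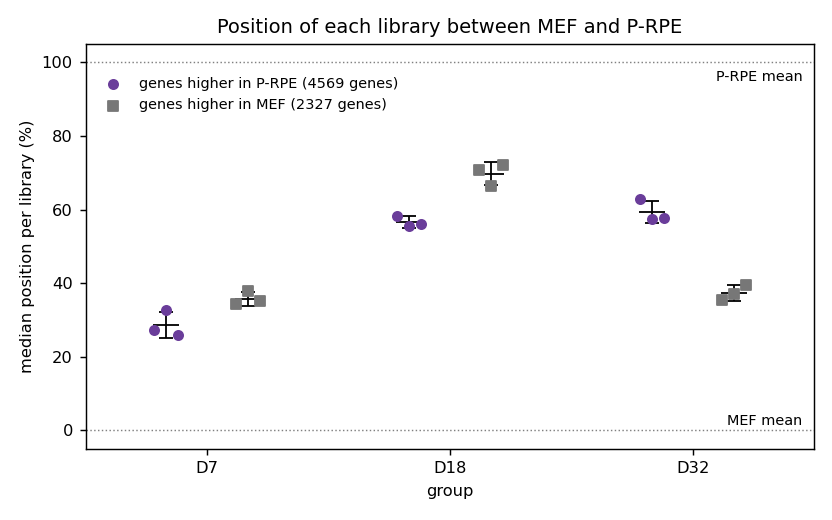
Median position of each library between the MEF mean (0%) and the P-RPE mean (100%) on the vertical axis, for the D7, D18 and D32 groups on the horizontal axis, over 4569 genes higher in P-RPE (circles) and 2327 genes higher in MEF (squares), with mean and SD (n = 3). On the MEF-higher genes the mean is 69.8% at D18 and 37.3% at D32.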

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

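The fits without the D32 or P-RPE libraries, the counts without genes that a P-RPE share could supply and the positions less such a share were chosen after the data were seen; the other alternatives were set before. Under RLE size factors, library totals, no filter, DESeq2, limma-voom and models of the 2 groups alone, each of the 6 counts of changed genes and the overlap of 9842 genes stayed within 1.5 times its value. With a mean of at least 5 CPM, P-RPE vs MEF gave 9578 genes because 12030 genes were tested. Leaving out 1 library at a time gave 10043 to 10588 genes for D7 vs MEF, 10425 to 11182 for D18 vs D7, 10355 to 11362 for D32 vs D18, 11124 to 12303 for D32 vs MEF, 8869 to 11113 for D32 vs P-RPE, 13106 to 13727 for P-RPE vs MEF and 8883 to 9694 for the overlap. Where P-RPE kept 1 library, that library is assumed to vary like the other groups. With the replicate number as a block, the counts were 11138, 11443, 11269, 12169, 10488 and 14241 in that order and the overlap 9639. The numbers showed no strong pairing: same-number libraries correlated after removal of group means by -0.0967 to 0.0953 over 26 pairs. Of 14 libraries, 7 correlated best with a library of their own number in another group. Whether the numbers mark a shared culture or day stays open. Without the D32 libraries, D7 vs MEF, D18 vs D7 and P-RPE vs MEF gave 11666, 12016 and 14630 genes. Without the P-RPE libraries, D7 vs MEF, D18 vs D7, D32 vs D18 and D32 vs MEF gave 11190, 11384, 11102 and 11964. Beyond the shifts given with the comparisons, the largest move of the median gene was -0.14 on the log2 scale, for P-RPE vs MEF without a filter. The next largest were 0.096 for P-RPE vs MEF with a mean of at least 5 CPM and 0.091 for D32 vs D18 with library totals. For the 4 comparisons of 3 against 3 libraries, the 10 splits of 6 libraries are too few for a share under 0.05: the real split called 11302, 11645, 11525 and 12376 genes, the highest other split 0, so 1 of the 10 was as large.

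The position values moved as well. For the P-RPE-higher genes at D7, D18 and D32, library totals gave 37.0%, 59.7% and 64.6%, a mean of at least 5 CPM gave 38.6%, 69.8% and 62.5%, and a prior count of 0.5 gave 33.2%, 60.8% and 63.1%. At D32, subtraction of a P-RPE share with library sizes left unchanged gave 40.4%. A signature threshold of 1 on the log2 scale gave 60.4% at D18, and 4 gave 22.3% at D7 and 44.7% at D18. For the MEF-higher genes, library totals gave 25.4%, 66.4% and 31.4%, a prior count of 0.5 gave 33.9%, 66.7% and 35.1%, and a mean of at least 5 CPM gave 66.6% at D18. A threshold of 1 gave 74.2% at D18 and 43.0% at D32, and 4 gave 63.1% and 34.5%. Leaving out MEF or P-RPE libraries gave 26.5% to 29.6%, 53.8% to 57.2% and 57.5% to 59.6% on the P-RPE-higher genes, and 34.4% to 35.9%, 65.0% to 69.7% and 35.3% to 38.12% on the MEF-higher genes. The cause was not tested.

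The log2 change turned sign for 6 results, none of which passed with all 14 libraries: with 1 library left out, Col1a1 in D18 vs D7 ran from -0.59 to 0.25 (without D18 replicate 3), Pax6 in D32 vs D18 from -0.44 to 0.032 (without D32 replicate 2), and Twist1 in D32 vs D18 from -0.31 to 0.22 (without D18 replicate 1), with 0.013 without D32 replicate 1 and 0.023 with library totals. In D32 vs P-RPE, Rax ran from -2.01 to 0.28 and Six6 from -1.40 to 1.18, both positive without P-RPE replicate 2, and Pax6 from -0.74 without P-RPE replicate 1 to 2.44, with -0.10 without D32 replicate 3. The cause was not tested. Of the results for named genes, 808 were the same with DESeq2 and 6 no longer passed, and over the models with 1 library left out 4417 were the same and 204 no longer passed. Of 94 camera calls, 94 ended with an estimated correlation, 2 with library totals, 1 with RLE size factors and 1 with fry. With 1 library left out, 15 retests no longer passed. No called list passed in the opposite direction in the settings run. At this depth 3 counts in a library correspond to 0.0682 to 0.0914 CPM, which limits what can be said of genes near 0.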

Other observations

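Single genes with high levels at D18 were picked after their values were seen, apart from Foxj1 and S100b. C3, a complement component, was at 10222 ± 2952 CPM at D18, against 1.5 ± 0.125 CPM in MEF, 784 ± 14.3 CPM at D7, 1016 ± 56.3 CPM at D32 and 20.3 ± 3.62 CPM in P-RPE. Lcn2, an iron-binding acute-phase protein, was at 4155 ± 1589 CPM at D18 and 429 ± 38.7 CPM at D32. S100b, a calcium-binding protein of astrocytes, rose from 5.16 ± 1.48 to 221 ± 54 CPM between D7 and D18. Fam216b, Zfp474 and Gas2l2 had 0 counts at D7 and rose to 122 ± 34.6, 21.8 ± 4.53 and 17.6 ± 3.24 CPM, beside the cilia factor Foxj1 at 649.9 ± 109 CPM. Of 195 genes of D18 that are low in MEF and P-RPE, the median D32 level was 10.3% of D18, and for 13 neural and glial list genes it was 6.72%. Apoe, a lipid carrier, was at 156 ± 4.85 CPM in MEF, 7741 ± 1369 CPM at D18 and 11764 ± 167 CPM in P-RPE, and Fth1, a subunit of the iron store ferritin, was at 807 ± 31.1 CPM in MEF and 7371 ± 1785 CPM at D18.

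Of 8 adipocyte markers, 7 were higher and 1 lower at D18 than at D7 (camera adjusted p = 0.108), with Plin1, a coat protein of lipid droplets, rising from 0.0773 ± 0.075 to 6.4 ± 3.92 CPM. Myh2 at D32 stood at 935 ± 401 CPM and Myh1, its neighbour among the fast myosins, at 19.8 ± 5.95 CPM after 0.167 ± 0.0591 CPM at D18, while Ckm, the creatine kinase of muscle, was at 0.279 ± 0.284 CPM and Myh4, another fast myosin, at 0.227 ± 0.162 CPM. The MEF libraries varied least, with a common biological coefficient of variation of 0.0426, against 0.158 at D7, 0.250 at D18, 0.214 at D32 and 0.218 in P-RPE.

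The tests for the patterns in this and the next paragraphs were all chosen after the results they explain were seen. RPE, red cell, endothelial and class II genes rose together at D32. Reads carried over from the P-RPE libraries are excluded as the only source of these genes in D32 replicates 1 and 2. There the rod genes lay at a median of at most 1.06% and 3.99% of either P-RPE library, and the RPE list genes at a 5th percentile of at least 10.5% and 6.97%. Carry-over as a part of the source stays open there. In D32 replicate 3 carry-over stays open even as the only source, since against P-RPE replicate 1 alone the rod genes lay at 6.32% and that percentile was 5.66%. Whether cells or RNA of eye tissue in the D32 libraries may be a source of these genes stays open, as does expression by the cultured cells, which was not tested: of 115 P-RPE-restricted genes, 87.0% lay within 2-fold of the median D32 fraction, and of 105 without the rod genes 95.2%. In 6 of 9 cases (3 classes in 3 libraries) the class median lay within the central 95% of the medians of sets of as many RPE list genes. Red cell genes lay below that range in replicate 1 (6.83% against at least 11.97%). Endothelial and class II genes lay above it in replicate 2 (15.7% against at most 14.9%, and 21.9% against at most 14.5%). The endothelial marker Emcn lay at 93.0%. These cases cannot decide, since the range holds the spread between genes within a library and not that between tissue samples. The P-RPE libraries themselves differed: the median ratio of replicate 1 to replicate 2 was 0.536 for red cell genes and 1.07 for RPE list genes.

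Hox genes fell together at D32, with a median of 17.5% of the D18 level over 24 genes. Dilution by P-RPE-like RNA alone is excluded, since its highest share would leave 85.2% and every D32 library had a median of at most 18.11%. The D32 libraries do not hold the mixture of animals' cells that the MEF libraries hold: Y-linked genes differed 7.48-fold between D32 libraries, and at most 1.23-fold within MEF, D7 or D18, so selection of few cells per culture and cells of other animals stay open. A loss of Hox expression in the cultured cells was not tested.

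P-RPE carried rod and red cell genes under an embryonic tissue label. The adult globins summed to 1334 CPM. Animals older than the tissue label says could account for this, as the embryonic globins Hbb-y, Hbb-bh1 and Hba-x made up 0.0121% of globin CPM in P-RPE, and red cells of midgestation embryos hold embryonic globin. How much rod RNA adhered to the tissue was not tested.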
